A study of Mus musculus with 2 samples.

How the data were processed

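Single-cell suspensions of mouse pancreas were captured on the BD Rhapsody system and sequenced in paired 150 bp reads on a Novaseq 6000, per the labels and the series' design text. The deposited matrices hold raw UMI counts per gene and cell barcode, not normalized, per the file headers and values. CASAVA 1.8, UMI-tools and Seurat and the genome build mm10 are named in the submitters' processing notes, without their roles. The aligner, the gene annotation and the rule that called cells are not given in the sources used here. Every barcode in both matrices held at least 501 UMIs, so a minimum may have been set before deposit.

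The matrices list 31253 genes with Ensembl identifiers and symbols. Of these identifiers, 31107 matched GENCODE vM21, an annotation of the same build, which gave the positions. For the 43 symbols found more than once, the entry with most UMIs was used. Groups were taken from the treatment labels, with 1 library each.

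Cells with at least 200 genes and at most 25% mitochondrial UMIs were kept. This removed 98 CP and 46 CP+EVs barcodes and left 13409 and 8799 cells. Scrublet, run per library with an expected doublet rate of 0.05, marked 0 and 1 cells. A caller marking under 0.5% of cells was taken as not having worked, so doublets were not removed, and mixed cells may remain. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 gave 34 clusters. Libraries were not integrated.

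Clusters were named from 23 marker lists. A marker counted when its log2 fold over the median cluster was above 1 and at least 10% of the cells had a UMI. At least 3 markers were needed, and a name was refused where leading genes belonged to another class, where at least 40% of an unrelated class's markers passed stricter limits, or where a cluster was shallow without own markers among its 10 leading genes. These thresholds were set after the data were seen, and the share of unnamed cells is given per library. Names mean that a cluster is like that type. Macrophage and monocyte clusters were merged.

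UMIs were summed per library and class and expressed as CPM of that sum, with exact Poisson 95% intervals. Log2 ratios are CP+EVs over CP with 0.5 counts added to each sum. Intervals of ratios are exact and conditional on the summed count, and shares of cells have exact Clopper-Pearson intervals. A gene at 0 in 1 library is given as a bound against 3 counts in that library. No test, p-value or count of changed genes was made, because cells are not replicates.

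The cell type markers, 30 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. List members were measured where CPM reached 20 in 1 library and the sum reached 20 UMIs. The percentile of a list's median places it among 10000 random lists matched on mean expression in 10 bins, as a description of these libraries. Its counting range comes from 1000 Poisson resamples. In the 6 largest classes with at least 100 cells per library, and in all kept cells, the 6 genes with the highest and the 6 with the lowest log2 ratio are named. They needed at least 100 CPM in 1 library and 100 UMIs in all, leaving out acinar enzyme, Reg, mitochondrial, haemoglobin, immunoglobulin, Gm and Rik genes. From the lists described, 1 to 4 members with large absolute ratios are named, together with Sting1, Cgas, Tbk1, Irf3 and Irf7. A gene of the B cell comparison that this rule takes is not reported here.

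Free RNA was read from markers of unrelated classes with at least 200 CPM in the library, as their level in a class relative to the library. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, leaving out shallower cells.

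The steps for ratios, intervals and percentiles were tested on simulated Poisson counts. These were drawn at the real totals around a profile shared by the libraries, with 200 changed genes. Exact Poisson intervals were thus nearly bound to cover the true ratio. The simulation held no variation between cells or libraries, so it checks the calculation and not how the intervals or percentiles behave in the real data. In simulated B cells (6643 genes) intervals excluded a ratio of 1 for 83.1% of 65 genes changed 1.5-fold, 95.3% of 64 changed 2-fold and 100% of 65 changed 4-fold, and covered the true ratio for 94.9% of unchanged genes. In simulated fibroblasts (6383 genes) they excluded 1 for 100% of genes at each size and covered the true ratio for 95.1% of unchanged genes. For fibroblast genes changed 1.5-fold, 2-fold and 4-fold they covered it in 92.3%, 89.6% and 95.5%. In simulated T cells they excluded 1 for 80%, 95.5% and 100% of genes at these sizes. Of 200 random lists in B cells, 5.5% fell under percentile 5 and 2% above percentile 95. Alternatives covered the filters on genes and mitochondrial UMIs, the clustering resolution and genes, the scaling, the mean of per-cell values, the minimum CPM of list members and the depth of thinning.

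Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.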

Results

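Gene expression was measured in single cells of mouse pancreas captured on the BD Rhapsody system. The series consists of 2 libraries, 1 from Cae-treated animals (CP) and 1 from Cae-treated animals that were also given extracellular vesicles (CP+EVs). The series title speaks of chronic pancreatitis and of vesicles induced by exercise, while the condition label of both libraries reads acute pancreatitis. The number of animals behind each library is not given in the sources used here. The CP library held 51652425 UMIs in 13507 barcodes with a median of 1417 UMIs per barcode. The CP+EVs library held 38532775 UMIs in 8845 barcodes with a median of 2884. With 1 library per group there was no test and no replicate check. All intervals cover counting error only, and every difference below compares these libraries, not the treatments.

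The series title names STING and interferon signalling, and the comparison asks which cells and which genes differed between the libraries. The libraries differed in which cells were captured. Neutrophil-like cells made up 19.5% of kept CP cells (95% interval 18.9 to 20.2, 2620 cells) and 0.261% of kept CP+EVs cells (0.166 to 0.392, 23 cells). Acinar-like cells, the enzyme-secreting cells of the pancreas, went the other way, with 0.0895% of kept CP cells (95% interval 0.0463 to 0.156, 12 cells) and 25.7% of kept CP+EVs cells (24.8 to 26.7, 2264 cells). Macrophage- or monocyte-like cells made up 23.3% of kept CP cells (95% interval 22.6 to 24.02, 3123 cells) and 8.74% of kept CP+EVs cells (8.16 to 9.35, 769 cells). B cell-like cells made up 3.10% of kept CP cells (95% interval 2.82 to 3.41, 416 cells) and 10.8% of kept CP+EVs cells (10.2 to 11.5, 952 cells).

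T cell-like cells made up 4.87% of kept CP cells (95% interval 4.51 to 5.25, 653 cells) and 5.68% of kept CP+EVs cells (5.21 to 6.19, 500 cells). Fibroblast-like cells made up 16.5% of kept CP cells (95% interval 15.9 to 17.1, 2212 cells) and 14.96% of kept CP+EVs cells (14.2 to 15.7, 1316 cells), and the log2 ratio of these shares turned from -0.14 to 0.40 with at least 500 genes per cell. The log2 ratio of the B cell share moved from 1.802 to 4.71 with acinar, Reg, mitochondrial, haemoglobin and immunoglobulin genes left out of the clustering, and that of the macrophage and monocyte share from -1.41 to -0.52 at Leiden resolution 0.5. Clusters that could not be named held 19.9% of kept CP cells (95% interval 19.2 to 20.6, 2665 cells) and 24.3% of kept CP+EVs cells (23.4 to 25.2, 2140 cells), at median depths of 702 and 798.5 UMIs. They were cluster 0 in CP and clusters 3 and 16 in CP+EVs. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. No sort or gate is named in the labels, and the gap in depth between the libraries can itself move these shares. Among immune cells alone, B cells were 5.23% in CP and 35.4% in CP+EVs, T cells 8.21% and 18.6%, macrophages or monocytes 39.3% and 28.6%, and neutrophils 32.9% and 0.856%.

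**Figure D1:**
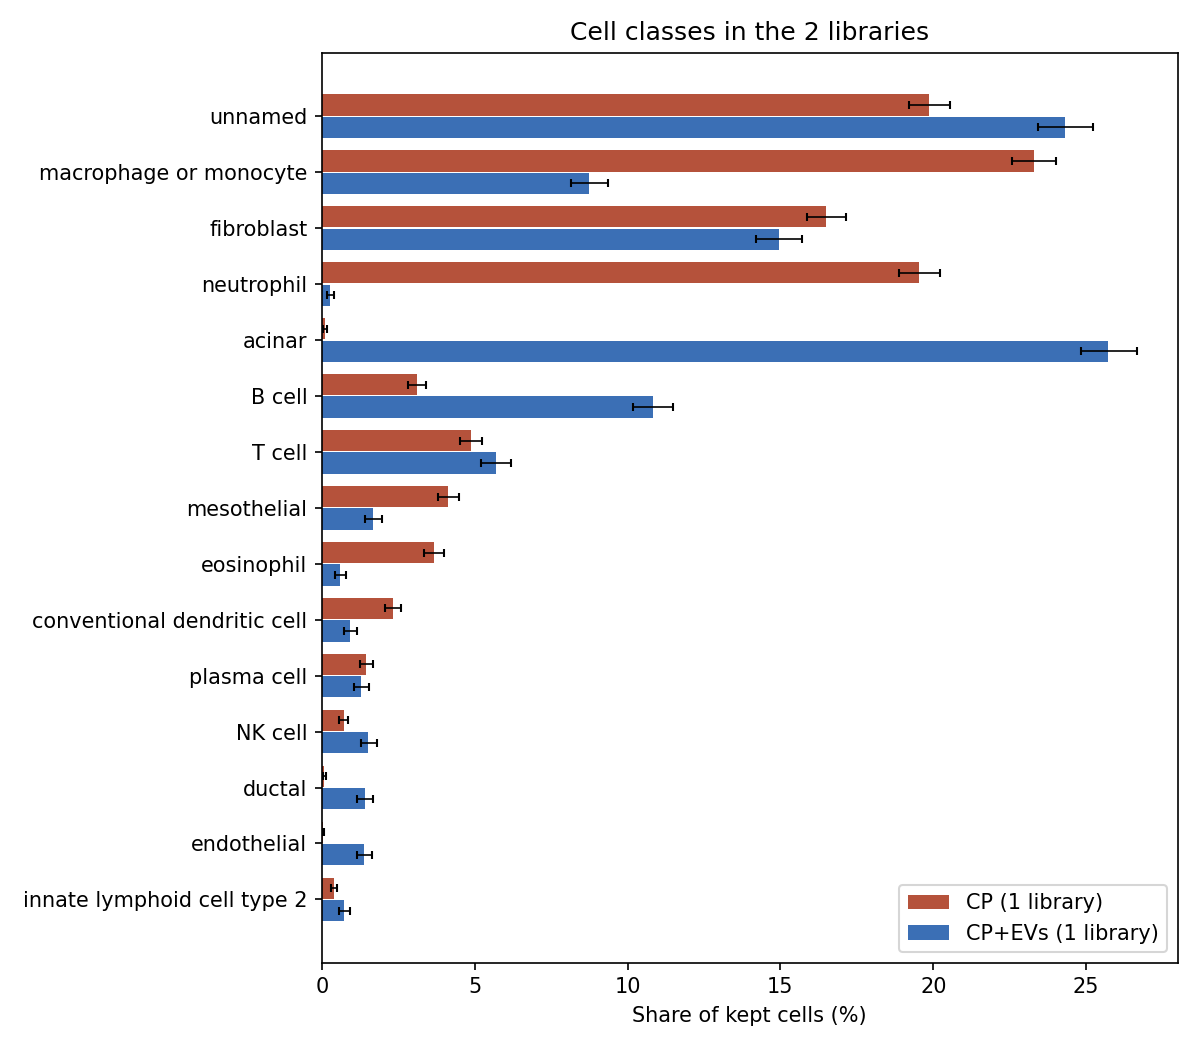
Share of kept cells in percent (horizontal axis) for each cell class (vertical axis) in the CP and CP+EVs libraries, 1 bar per library, with exact 95% binomial intervals as whiskers. Neutrophils fell from 19.5% to 0.261% and acinar cells went from 0.0895% to 25.7%.

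Free RNA differed between the libraries and bears on every class. Acinar enzyme and Reg genes took 0.0826% of CP UMIs and 17.0% of CP+EVs UMIs. In T cells, which do not make them, they took 0.0179% and 4.37%. Markers of unrelated classes reached at least 14.5% of their library level in CP T cells and 9.05% in CP+EVs T cells. Genes near that level in a class are therefore read as background there. Examples outside the macrophage and monocyte class are S100a8 and S100a9 of neutrophils, Tff2, Lyz1 and Retnla.

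Fibroblasts of the CP+EVs library carried less RNA of Saa3, Lcn2, Timp1 and Prg4 and more RNA of the interferon gamma list. Saa3, an acute-phase serum amyloid, stood at 2148 CPM (2126 to 2171) in CP and 2.88 CPM (1.95 to 4.12) in CP+EVs. Lcn2, the iron-binding lipocalin, was lower (147-fold, 108 to 204), as were Timp1, an inhibitor of metalloproteinases (18.1-fold, 16.4 to 19.9), and Prg4 (16.8-fold, 13.3 to 21.5). Higher in CP+EVs were the methyltransferase Inmt (13.2-fold, 11.7 to 14.95), Efhd1 (10.6-fold, 9.20 to 12.4), the proprotein convertase Pcsk6 (9.54-fold, 9.05 to 10.1) and Igfbp5 (8.62-fold, 8.25 to 9.02). With means of per-cell values the log2 ratio moved from -9.52 to -10.11 for Saa3 and from 3.41 to 4.03 for Efhd1. Tff2 and Retnla were also higher, and S100a8 and S100a9 lower, each at between 11.5% and 22.5% of its library level, within reach of free RNA. Clusters 7 and 8 held most fibroblasts in CP and cluster 6 in CP+EVs, and the median depth was 2060 and 7040.5 UMIs per cell.

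The interferon gamma list had 15 of 20 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs in fibroblasts (median log2 ratio 0.98, counting range 0.90 to 1.05, percentile 100). Its largest ratios were those of the chemokine Cxcl9 (6.81-fold, 6.17 to 7.53), Tgtp1 (3.66-fold, 2.88 to 4.67) and the guanylate-binding protein Gbp4 (2.94-fold, 2.39 to 3.64). The type I interferon-stimulated list was close to level, with 8 of 40 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.24, counting range 0.15 to 0.30, percentile 98.6), and its members went both ways, as Ifit2 (log2 ratio 1.43, 24.1 and 64.97 CPM) and Isg15 (log2 ratio -1.12, 32.01 and 14.7 CPM) show. MHC class I genes had 5 of 15 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.53, counting range 0.50 to 0.56, percentile 99.9), led by H2-Q6 (log2 ratio 1.27, 18.8 and 45.5 CPM), whose reads may be shared with H2-Q7, and H2-Q4 (log2 ratio 1.10, 13.4 and 28.8 CPM).

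Matrix genes had 6 of 42 measured members at least 1.5-fold higher and 16 at least 1.5-fold lower in CP+EVs in fibroblasts (median log2 ratio -0.26, counting range -0.35 to -0.19, percentile 0.590). Tenascin C, Tnc, was lower (36.7-fold, 23.6 to 60.3), while the inhibitors Timp3 (7.31-fold, 6.54 to 8.20) and Timp2 (3.99-fold, 3.93 to 4.06) were higher. The stellate and myofibroblast list had 2 of 14 measured members at least 1.5-fold higher and 4 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.26, counting range -0.34 to -0.17, percentile 4.03), with the lowest ratios for the smooth muscle actin Acta2 (25.3-fold, 13.6 to 53.2) and Cthrc1 (11.3-fold, 8.95 to 14.6). Chemokines had 2 of 17 measured members at least 1.5-fold higher and 12 at least 1.5-fold lower in CP+EVs (median log2 ratio -1.47, counting range -1.53 to -1.30, percentile 0), among them Cxcl5 (15.5-fold, 10.04 to 25.3) and the B cell attractant Cxcl13 (7.17-fold, 6.39 to 8.07). The NF-kB list had 1 of 16 measured members at least 1.5-fold higher and 8 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.66, counting range -0.80 to -0.61, percentile 0.010000), but its lowest members Nlrp3 (log2 ratio -3.98, 82.6 and 5.19 CPM) and Il1b (log2 ratio -3.23, 259.7 and 27.7 CPM) stood at 15.9% and 12.6% of their library level in CP, within reach of free RNA. ER stress genes had 1 of 23 measured members at least 1.5-fold higher and 11 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.58, counting range -0.64 to -0.56, percentile 0.010000). Pdia4 (log2 ratio -1.51, 421 and 148 CPM) and Calr (log2 ratio -1.43, 2716 and 1008 CPM) were lowest. Glycolysis genes had 4 of 15 measured members at least 1.5-fold higher and 9 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.91, counting range -0.98 to -0.81, percentile 0). Gapdh (log2 ratio -1.67, 207 and 65.2 CPM) and Hif1a (log2 ratio -1.46, 219 and 79.97 CPM) lay lowest there. Immediate early and dissociation stress genes had 9 of 30 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.18, counting range 0.15 to 0.21, percentile 92.2).

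Macrophages and monocytes of the CP+EVs library carried more MHC class II RNA and less RNA of Arg1 and Chil3. Macrophage and monocyte clusters are merged here, Chil3 is a listed monocyte marker, and H2-DMb2 of the class II list is a listed dendritic cell marker. A different mixture of cells between the libraries may therefore give part of these differences, which was not tested. Arg1, the arginase of alternatively activated macrophages, stood at 268 CPM (259.97 to 276) in CP and 0.835 CPM (0.228 to 2.14) in CP+EVs. Chil3, a chitinase-like protein, stood at 1179 CPM (1162 to 1196) in CP and 13.4 CPM (10.3 to 17.1) in CP+EVs. Retnla, a resistin-like protein of the same activation programme, went the other way with 337 CPM (327 to 346) in CP and 12056 CPM (11958 to 12155) in CP+EVs. Saa3 (196-fold, 127 to 320.2) and the carbonic anhydrase Car2 (77.5-fold, 42.1 to 162) were lower. Saa3 stood at 47.8% of its library level in CP, above the 28.4% of neutrophil markers and the 10.1% of fibroblast markers in this class. In CP it stood at 126% of its library level in fibroblasts and 535% in mesothelial cells. Free RNA may give part of the Saa3 level in macrophages and monocytes, and how much was not tested. With means of per-cell values the log2 ratio moved from -8.16 to -8.97 for Arg1 and from -6.21 to -4.997 for Car2, and with at least 500 genes per cell that of Retnla from 5.16 to 5.98. Lyz1 (92.7-fold, 86.9 to 99.1), which may share reads with Lyz2, Hr (84.8-fold, 60.5 to 123), Gbp2b (50.5-fold, 36.2 to 72.4), close in sequence to Gbp2, and Cd2 (22.2-fold, 17.6 to 28.3) were higher. S100a8, S100a9 and Tff2 stood at between 11.02% and 28.4% of their library level. In CP, S100a8 and S100a9 stood at 28.4% and 24.8%, above the 10.1% of fibroblast markers in this class. Whether they are free RNA or RNA of this class was not tested.

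MHC class II genes had 9 of 11 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs in this class (median log2 ratio 2.04, counting range 1.96 to 2.06, percentile 100), with H2-DMb2 (17.6-fold, 15.7 to 19.8), H2-Eb1 (5.37-fold, 5.30 to 5.45) and H2-Ab1 (4.84-fold, 4.78 to 4.90) in the lead. The interferon gamma list had 10 of 21 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.57, counting range 0.47 to 0.69, percentile 100), led by Cxcl9 (9.51-fold, 8.36 to 10.8) and Gbp8 (5.82-fold, 4.25 to 8.03). The type I interferon-stimulated list lay on the other side, with 2 of 42 measured members at least 1.5-fold higher and 18 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.46, counting range -0.54 to -0.39, percentile 0.520). Its largest ratios were those of Cxcl10 (log2 ratio 2.08, 37.8 and 159.997 CPM), Ifi207 (log2 ratio -1.34, 491 and 194 CPM) and Isg15 (log2 ratio -1.32, 31.002 and 12.3 CPM). The median over all 6497 genes measured in this class was -0.24, and median-of-ratios scaling moved it by 0.20, so that small list medians here are set by the scaling.

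The alternatively activated list held members at both extremes, with 4 of 13 measured members at least 1.5-fold higher and 6 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.19, counting range -0.41 to -0.03, percentile 57.5), a median that stood at -2.07 among members of at least 100 CPM and at 0.00699 with median-of-ratios scaling. The pro-inflammatory list did too, with 3 of 14 measured members at least 1.5-fold higher and 4 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.28, counting range -0.37 to -0.19, percentile 33.3), its ends being the Fc receptor Fcgr1 (13.97-fold, 11.3 to 17.5) and Cxcl9. NF-kB genes had 9 of 22 measured members at least 1.5-fold higher and 5 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.33, counting range 0.19 to 0.38, percentile 99.99), with Il6 (6.63-fold, 6.07 to 7.24) and Vcam1 (5.98-fold, 4.56 to 7.89) furthest from level, but that median turned to -0.033 with means of per-cell values. Chemokines had 6 of 15 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.41, counting range 0.38 to 0.45, percentile 99.9). Cxcl9 lay furthest up and Ccl12 (log2 ratio -2.30, 45.6 and 9.19 CPM) furthest down. MHC class I genes had 4 of 15 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.35, counting range 0.24 to 0.46, percentile 99.9). H2-Q6 (log2 ratio 2.83, 23.9 and 170.2 CPM) and H2-Q7 (log2 ratio 1.91, 65.3 and 245 CPM), which may share reads, led them. Immediate early and dissociation stress genes, which handling can raise, had a median of like sign and size, with 11 of 30 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.39, counting range 0.36 to 0.44, percentile 99.99), led by Hspa1b (log2 ratio 2.31, 162 and 802 CPM) and Egr3 (log2 ratio 2.13, 36.1 and 158 CPM). Glycolysis genes had 1 of 16 measured members at least 1.5-fold higher and 9 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.73, counting range -0.84 to -0.60, percentile 0.020000). The lowest were Gapdh (log2 ratio -1.53, 476 and 165 CPM) and Vegfa (log2 ratio -1.46, 113 and 40.7 CPM). Clusters 4 and 5 held most of the class in CP and clusters 12 and 24 in CP+EVs.

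B cells showed the lowest type I interferon-stimulated list among the 6 classes compared. It had 0 of 44 measured members at least 1.5-fold higher and 39 at least 1.5-fold lower in CP+EVs (median log2 ratio -1.48, counting range -1.64 to -1.38, percentile 0). Ifit1, which binds viral RNA, stood at 104 CPM (85.7 to 125) in CP and 3.47 CPM (2.09 to 5.43) in CP+EVs. The antiviral radical SAM enzyme Rsad2 (25.2-fold, 14.6 to 46.2), Ifit3 (18.3-fold, 12.99 to 26.3) and Ifit3b (19.9-fold, 10.1 to 42.8) followed, the last pair being close copies whose reads may be shared. The interferon gamma list had 1 of 20 measured members at least 1.5-fold higher and 10 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.51, counting range -0.63 to -0.29, percentile 0.020000). Its lowest members were Tgtp1 (log2 ratio -1.95, 40.1 and 10.4 CPM) and Irgm1 (log2 ratio -1.85, 176 and 48.8 CPM). Immediate early and dissociation stress genes had 3 of 30 measured members at least 1.5-fold higher and 12 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.38, counting range -0.46 to -0.25, percentile 0.010000), and their median was 0.0084 in the clusters led by Ighd. Cell cycle genes had 23 of 23 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs (median log2 ratio 1.86, counting range 1.71 to 1.98, percentile 100), with Cdc20 (6.67-fold, 3.34 to 15.6), Rrm2 (4.76-fold, 3.73 to 6.16) and Cdk1 (4.77-fold, 3.42 to 6.86) in the lead. In the clusters led by Ighd alone that median was 0.34.

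Gcsam (11.04-fold, 6.42 to 20.8) and Mybl1 (6.96-fold, 5.32 to 9.27) were among the genes with the highest ratios in B cells. Saa3, S100a8, S100a9, Lcn2 and Ifitm1 were lower and stood at between 13.4% and 30.3% of their library level in CP. Tff2 (at least 72.5-fold), Lyz1 and Retnla were higher, at between 12.2% and 14.2% of their library level in CP+EVs. The NF-kB list had 0 of 18 measured members at least 1.5-fold higher and 12 at least 1.5-fold lower in CP+EVs (median log2 ratio -1.06, counting range -1.40 to -0.85, percentile 0), led by Nlrp3 (log2 ratio -4.22, 124 and 6.58 CPM) and Il1b (log2 ratio -3.89, 381 and 25.6 CPM). In CP these stood at 23.9% and 18.5% of their library level, near the 22.1% of neutrophil markers in CP B cells and thus within reach of free RNA. Cluster 14 held most B cells in CP and clusters 9, 18 and 28 in CP+EVs. In the clusters led by Ighd alone the interferon-stimulated median was -0.92.

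In T cells the medians of both interferon lists lay nearer level than in B cells. The type I interferon-stimulated list had 0 of 41 measured members at least 1.5-fold higher and 11 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.12, counting range -0.30 to -0.05, percentile 8.22), with Rsad2 (3.91-fold, 2.39 to 6.71) and Ifit3 (2.48-fold, 1.59 to 3.97) lowest, and its median turned to 0.07 among members of at least 100 CPM. The interferon gamma list had 1 of 22 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.08, counting range 0.0022 to 0.21, percentile 95.5), with Gbp3 (log2 ratio -0.71, 55.2 and 33.6 CPM) and Irf8 (log2 ratio 0.64, 19.4 and 30.3 CPM) furthest from level. Irf8 stood at 28.3% and 25.5% of its library level. Immediate early and dissociation stress genes had 3 of 30 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.11, counting range 0.03 to 0.17, percentile 99.6). Cytotoxic genes had 5 of 16 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.39, counting range 0.30 to 0.52, percentile 100), led by the transcription factor Eomes (2.11-fold, 1.69 to 2.65) and the receptor Klrk1 (1.799-fold, 1.52 to 2.14). Both are also listed NK cell markers, and NK cells went from 0.708% to 1.52% of kept cells. Whether NK-like cells in this class or a different mixture of T cells gave the higher list was not tested. Checkpoint and regulatory genes had 0 of 12 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.12, counting range -0.25 to 0.13, percentile 18.3), with Il10 (4.03-fold, 2.37 to 7.28) and Ctla4 (log2 ratio -0.56, 200.3 and 135 CPM) lowest. The heat shock genes Hspa1a (3.65-fold, 2.92 to 4.60) and Hspa1b (3.49-fold, 3.01 to 4.06), near-identical copies, and the integrin Itga1 (2.60-fold, 2.14 to 3.17) were higher.

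Genes with the lowest ratios in T cells were Saa3, Slfn4 (139-fold, 38.1 to 1152), S100a9, Trem1 (82.7-fold, 27.998 to 403), S100a8 and Ifitm1 (46.9-fold, 21.3 to 129), at between 14.9% and 37.6% of their library level in CP. Tff2 (at least 248-fold), Lyz1 and Retnla were highest, at between 13.2% and 24.1% in CP+EVs. NF-kB genes had 0 of 20 measured members at least 1.5-fold higher and 12 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.89, counting range -1.13 to -0.62, percentile 0), and the median was also -0.89 with the 2 members at 0 in CP+EVs placed at their bound. These were Il1a (at least 13.8-fold lower) and Il23a (at least 12.3-fold lower). Nlrp3 (log2 ratio -4.41, 205 and 9.35 CPM) and Il1b (log2 ratio -3.66, 566 and 44.6 CPM) followed, at 39.6% and 27.5% of their library level in CP. MHC class II genes, which mouse T cells do not normally make, had 8 of 10 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs (median log2 ratio 1.03, counting range 0.80 to 1.19, percentile 100), and H2-Aa, H2-Ab1, H2-Eb1 and Cd74 stood at between 14.6% and 17.9% of their library level. That median was 2.501 with free RNA removed and 0.31 with at least 500 genes per cell. Cluster 11 held most T cells in CP and clusters 17 and 22 in CP+EVs.

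The CPM of Sting1 itself, the adaptor that senses cyclic dinucleotides, was lower in CP+EVs in each of these 4 classes, while shares of cells with a Sting1 UMI did not all follow. It stood at 45.5 CPM (42.3 to 48.9) in CP and 19.4 CPM (16.8 to 22.3) in CP+EVs in fibroblasts. In macrophages and monocytes it stood at 111 CPM (105 to 116) in CP and 72.1 CPM (64.7 to 80.1) in CP+EVs. B cells had 69.2 CPM (54.6 to 86.7) in CP and 47.7 CPM (42.1 to 53.9) in CP+EVs. T cells had 73.5 CPM (62.3 to 86.2) in CP and 56.7 CPM (46.3 to 68.7) in CP+EVs, with overlapping intervals. Sting1 (ENSMUSG00000024349, protein coding) lies on chromosome 18, 35733679 to 35740554, minus strand of mm10. The sensor Cgas (ENSMUSG00000032344, chromosome 9, 78430526 to 78443237, minus strand) had log2 ratios of -0.20 in fibroblasts, -0.42 in macrophages and monocytes, -1.04 in B cells and -0.37 in T cells. Tbk1 (log2 ratio 0.02, -0.71, -0.72 and 0.04 in the same order), Irf3 (0.45, 0.35, -0.03 and 0.22) and Irf7 (-0.10, -0.16, -1.20 and 0.01) had no common direction. With means of per-cell values the log2 ratio turned to -0.48 for Tbk1 in fibroblasts and moved to -2.25 for Cgas in B cells. In B cells, 10 of 416 CP and 19 of 952 CP+EVs cells had a Cgas UMI. Without thinning these shares were 2.40% (1.16 to 4.38) and 1.996% (1.21 to 3.099), with overlapping intervals. Unthinned shares were higher in CP+EVs in fibroblasts (5.88% and 6.46%) and in macrophages and monocytes (19.7% and 20.9%). In T cells they were 7.66% and 7.4%. After thinning to 1000 UMIs, Cgas shares were lower in CP+EVs in these 4 classes, with overlapping intervals.

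The list of STING and interferon pathway components had 1 of 20 measured members at least 1.5-fold higher and 8 at least 1.5-fold lower in CP+EVs in B cells (median log2 ratio -0.44, counting range -0.55 to -0.29, percentile 0.180). That median was -0.04 in the B cell clusters led by Ighd and -0.09 with means of per-cell values. Macrophages and monocytes had 1 of 20 measured members at least 1.5-fold higher and 6 at least 1.5-fold lower in CP+EVs (median log2 ratio -0.19, counting range -0.32 to -0.11, percentile 66.2), close to the median of all genes there, and the list median turned to 0.0081 with median-of-ratios scaling. Fibroblasts had 4 of 19 measured members at least 1.5-fold higher and 3 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.28, counting range 0.04 to 0.34, percentile 95.8), which turned to -0.08 with means of per-cell values. T cells had 1 of 22 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower in CP+EVs (median log2 ratio 0.03, counting range -0.07 to 0.13, percentile 80.97). Besides Sting1, the largest ratios were those of Enpp1 (log2 ratio 1.23, 8.93 and 21.05 CPM) and the interferon receptor chain Ifnar2 (log2 ratio -0.998, 73.2 and 36.6 CPM) in fibroblasts, of Ikbke (log2 ratio -1.58, 60.8 and 20.3 CPM) and Ifnar2 (log2 ratio -1.32, 118 and 47.2 CPM) in macrophages and of Stat2 (log2 ratio -1.43, 175 and 65.1 CPM) in B cells.

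After thinning to 1000 UMIs, 10.4% of CP macrophages and monocytes (9.09 to 11.8) and 6.20% of CP+EVs ones (4.42 to 8.41) had a Sting1 UMI. Thinned to 500 UMIs, which keeps the shallow cells, the shares were 4.55% and 4.55%. Without thinning they were 29.7% and 26.4%. Of fibroblasts, 4.66% (3.66 to 5.85) and 1.60% (0.996 to 2.44) had a UMI after thinning to 1000, and 20.3% and 12.5% without. Thinned to 500 UMIs, the fibroblast shares were 1.90% (1.37 to 2.56) and 1.14% (0.639 to 1.87), with overlapping intervals. Intervals overlapped in B cells, with 7.23% (4.73 to 10.5) and 4.91% (3.60 to 6.51) after thinning to 1000 UMIs. Without thinning the B cell shares were 13.9% and 19.01%, the other way round, at median depths of 2118 and 3597.5 UMIs. In T cells they were 7.75% (5.68 to 10.3) and 5.82% (3.90 to 8.30) after thinning to 1000, also overlapping, and 18.7% and 16.8% without. The median depths of the thinned cells had been 6111.5 and 6127 UMIs in macrophages and monocytes, and 7121.5 and 7058 in fibroblasts. For comparison, 1.23% of CP+EVs acinar cells and 1.59% of CP neutrophils had one, at median depths of 2932 and 2009 UMIs. The CP+EVs fibroblast share at 1000 UMIs lay close to both, but this cannot tell expression from free RNA. Whether those classes lack Sting1 was not tested, and the neutrophils were of the other library. Markers of unrelated classes also stood higher in CP+EVs acinar cells (18.9% to 42.7% of their library level) than in CP+EVs fibroblasts (10.8% to 13.9%). Thinning left out 1059 CP and 156 CP+EVs macrophages and monocytes, 690 and 7 fibroblasts, 70 and 35 B cells, and 85 and 19 T cells.

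**Figure D2:**
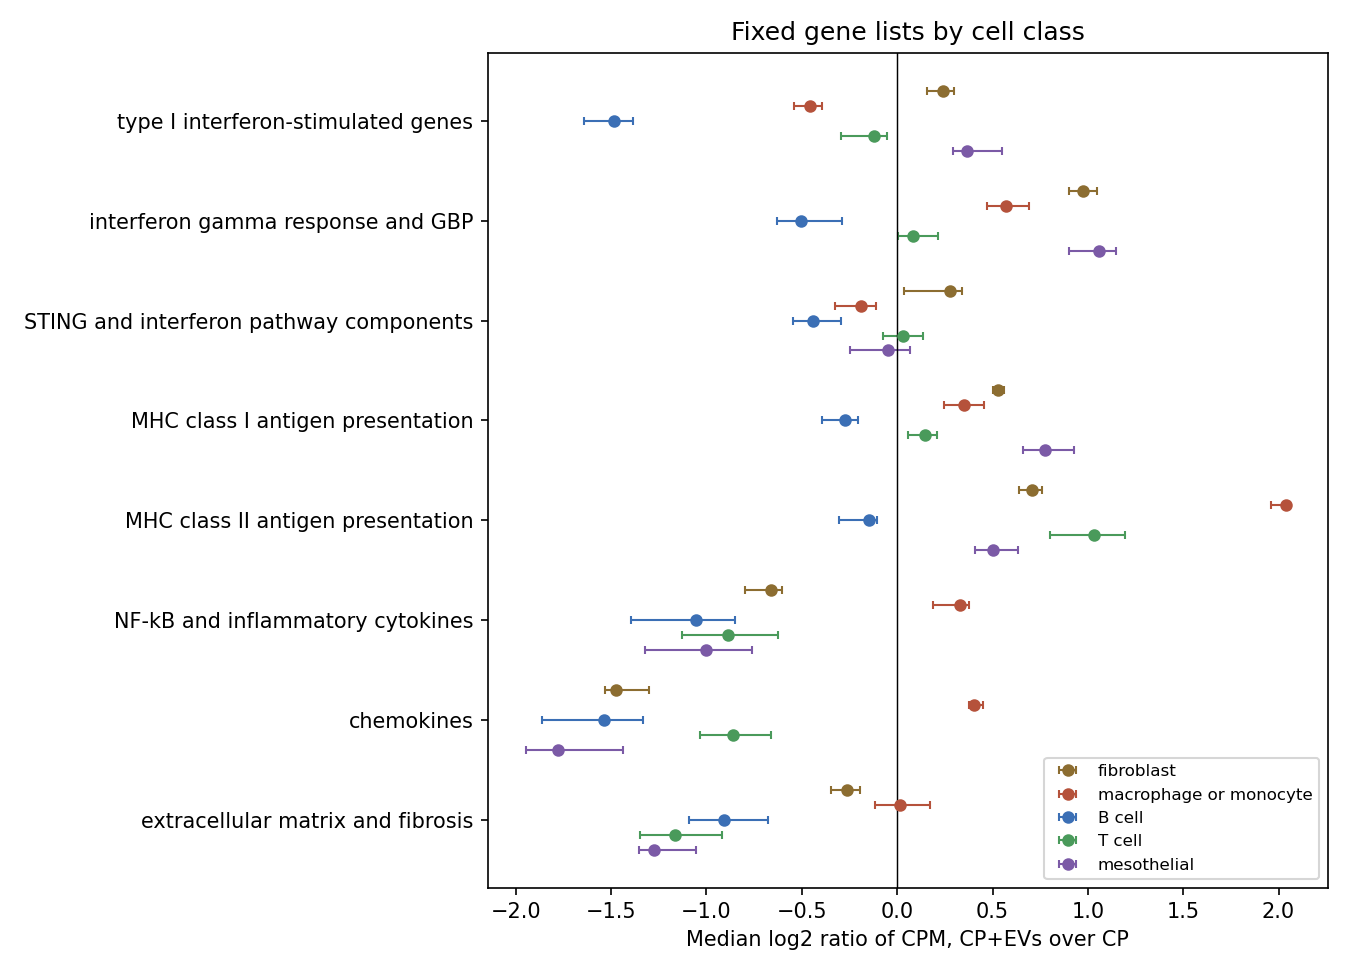
Median log2 ratio of CPM, CP+EVs over CP (horizontal axis), of 8 fixed gene lists (vertical axis) in 5 cell classes, with whiskers for the 95% range under Poisson resampling. In the top row B cells lie at -1.48 and mesothelial cells at 0.37, and the fibroblast interferon gamma list lies at 0.98.

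Over the sum of all kept cells, ratios mix the shares of the classes with differences within them, such as those of Saa3 in fibroblasts and Chil3 in macrophages. Serpini2 (671-fold, 413 to 1175), Tff2 (385-fold, 335 to 445), Cuzd1 (247-fold, 188 to 330.4), Pdia2 (203-fold, 151 to 279.6), Tmed6 (102-fold, 77.5 to 136) and the cholecystokinin receptor Cckar (99.6-fold, 75.8 to 134) were higher in CP+EVs. Saa3 (604-fold, 500.5 to 735), Chil3 (198-fold, 161 to 247), Asprv1 (106-fold, 79.6 to 143), Il1f9 (104-fold, 78.7 to 139) and the neutrophil receptors Cxcr2 (67.4-fold, 58.5 to 78.2) and Csf3r (59.2-fold, 51.3 to 68.7) were higher in CP. In mm10, Saa3 (ENSMUSG00000040026) lies on chromosome 7, 46711998 to 46715700, minus strand, Ifit1 (ENSMUSG00000034459) on chromosome 19, 34640871 to 34650009, plus strand, Arg1 (ENSMUSG00000019987) on chromosome 10, 24915221 to 24927484, minus strand and Cxcl9 (ENSMUSG00000029417) on chromosome 5, 92321347 to 92328079, minus strand, and all 4 are annotated as protein coding.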

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

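Among the tests in this part, those of free RNA, of the clusters led by Ighd and of T cells were chosen after the data were seen, and those of free RNA and of T cells after the result itself.

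Medians of interferon lists lay on opposite sides of 0 in different cell classes of the same libraries. The difference between classes was not tested. For the type I interferon-stimulated list, the mesothelial median of 0.37 and the B cell median of -1.48 lay 1.85 apart on the log2 scale. For the interferon gamma list, the mesothelial median of 1.06 and the B cell median of -0.51 lay 1.57 apart. For the STING and interferon pathway components, the fibroblast median of 0.28 and the B cell median of -0.44 lay 0.72 apart, but with means of per-cell values these were -0.077 and -0.086, on the same side, and the B cell median was -0.045 in the clusters led by Ighd.

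The lower type I interferon-stimulated list in CP+EVs B cells was weighed further. The median was -1.68 with free RNA removed, which cannot decide on free RNA of other cells. Removal used the lowest source level, 11.8% of the library level in CP B cells, where neutrophil markers stood at 22.1%. It also cut off negative sums, and the log2 ratio of Ifit1 went from -4.87 to -10.1. A shift of like size across the whole library is argued against, since the T cell median was -0.12 (-0.30 to -0.05). A smaller shift in some classes stays open, as other medians ranged from -0.46 in macrophages and monocytes to 0.37 in mesothelial cells. A different mixture of B cells stays open. In the clusters led by Ighd, with 400 CP and 657 CP+EVs cells, the median was -0.92 (-1.09 to -0.83). That lies between the limits set for a mixture, above -0.5 if it were the cause and below -1 if not. Cluster 14 held most of these CP cells and cluster 9 most of these CP+EVs cells. The kind of B cell was thus not held equal, and a median below -1 could not have excluded every mixture. Part of the difference may therefore come from the CP+EVs B cells outside these clusters. An effect of the vesicles was not tested apart from the library, with 1 library per group.

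Outside the named classes, unnamed cluster 16 held 3.38% of kept CP+EVs barcodes (297 cells, 3.01 to 3.77). They combined acinar genes, with 44.5% of UMIs from acinar enzyme and Reg genes, and the B cell marker Cd79a at 75.0 CPM against 34.9 CPM in the whole library. Doublets of acinar and B cells were not removed and stay open as a source of this combination, which was not tested.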

How the results depend on the processing

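Free RNA removal, leaving out the top 5% of doublet scores, leaving out shallow clusters, the B cell clusters led by Ighd and cells of at least 1000 UMIs were alternatives chosen after seeing the data. Of 1686 values of 154 list medians under 13 alternatives, 1607 kept the direction, 361 left the counting range and 39 reversed a direction whose range had excluded 0. For shares of cell classes, 101 of 107 values kept the direction, 22 left their interval and 4 reversed. For named genes, 364 of 374 kept the direction and 41 left their interval. Most of these genes were picked for the highest or lowest ratios, so a kept direction was nearly fixed in advance. Of 144 shares of cells with a UMI, 117 left their interval, as thinning sets their level. Keeping doublets gave the main values, since none were removed, and says nothing about stability. The cause of the changes below was not tested, except that shares of immune cells have another denominator. Counting intervals are wider where a class holds fewer summed UMIs. No paired analysis was possible because each group has 1 library and no label pairs them. Values below are log2 ratios or list medians, from the main value to the alternative.

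With acinar, Reg, mitochondrial and haemoglobin genes out of the totals, MHC II in macrophages went from 2.04 to 2.09 and interferon-stimulated in T cells from -0.12 to -0.049. With those genes and immunoglobulin genes out of the clustering, the B cell share went from 1.802 to 4.71, the T cell share from 0.22 to 0.41 and the macrophage share from -1.41 to -1.18. No list median, that of interferon-stimulated genes in B cells included, was computed under that clustering. With only the B cell clusters led by Ighd, MHC I in B cells went from -0.27 to 0.14, MHC II in B cells from -0.15 to 0.14 and STING in B cells from -0.44 to -0.045. Glycolysis in B cells went from 0.28 to -0.33, immediate early in B cells from -0.38 to 0.0084 and immunoglobulin in B cells from 0.19 to -0.20 under the same setting. Interferon-stimulated in B cells went from -1.48 to -0.92 under the same setting. At Leiden resolution 0.5, the fibroblast share went from -0.14 to 0.32, the macrophage share from -1.41 to -0.52 and MHC II in macrophages from 2.04 to 1.95. At Leiden resolution 2, the macrophage share went from -1.41 to -1.92 and MHC II in macrophages from 2.04 to 2.09. With cells of at least 1000 UMIs, the fibroblast share went from -0.14 to 0.081. With at least 500 genes per cell, the B cell share went from 1.802 to 1.98, the fibroblast share from -0.14 to 0.40 and the mesothelial cell share from -1.30 to 2.08. MHC II in macrophages went from 2.04 to 2.14, immunoglobulin in fibroblasts from 0.13 to -0.059 and interferon gamma in fibroblasts from 0.98 to 0.78 under the same setting. With at most 10% mitochondrial UMIs, the fibroblast share went from -0.14 to -0.037. With free RNA removed, MHC II in fibroblasts went from 0.71 to -0.38, STING in fibroblasts from 0.28 to 0.38 and ductal in T cells from -0.34 to 0.15. Alternative macrophage in T cells went from -0.82 to 0.099, alternative macrophage in fibroblasts from -0.08 to 0.36 and chemokines in T cells from -0.86 to 0.62 under the same setting. Complement in T cells went from -0.74 to 0.055, complement in mesothelial cells from 0.08 to -0.036 and matrix in T cells from -1.16 to 0.099 under the same setting. Immunoglobulin in fibroblasts went from 0.13 to -0.45, immunoglobulin in mesothelial cells from -0.63 to 0.33 and interferon gamma in fibroblasts from 0.98 to 1.05 under the same setting. Lysosome in T cells went from -0.26 to 0.15, oxidative stress in fibroblasts from -0.04 to 0.056 and interferon-stimulated in B cells from -1.48 to -1.68 under the same setting. Interferon-stimulated in T cells went from -0.12 to -0.026 and interferon-stimulated in fibroblasts from 0.24 to 0.30 under the same setting. With means of per-cell values, MHC II in macrophages went from 2.04 to 1.95, NF-kB in macrophages from 0.33 to -0.033 and STING in B cells from -0.44 to -0.086. STING in fibroblasts went from 0.28 to -0.077, glycolysis in B cells from 0.28 to -0.11 and immunoglobulin in fibroblasts from 0.13 to -0.30 under the same setting. Interferon gamma in fibroblasts went from 0.98 to 0.70, interferon-stimulated in B cells from -1.48 to -1.17 and interferon-stimulated in fibroblasts from 0.24 to 0.023 under the same setting. Interferon-stimulated in macrophages went from -0.46 to -0.35 under the same setting. With median-of-ratios scaling, MHC II in macrophages went from 2.04 to 2.24, STING in macrophages from -0.19 to 0.0081 and STING in plasma cells from -0.25 to 0.074. Alternative macrophage in macrophages went from -0.19 to 0.00699, cell death in macrophages from -0.10 to 0.10 and complement in mesothelial cells from 0.08 to -0.0039 under the same setting. Ribosomal in macrophages went from -0.10 to 0.10, immediate early in plasma cells from -0.28 to 0.051 and interferon gamma in macrophages from 0.57 to 0.77 under the same setting. Lysosome in plasma cells went from -0.25 to 0.079, mitochondrial in plasma cells from -0.10 to 0.23 and oxidative stress in macrophages from -0.16 to 0.043 under the same setting. Interferon-stimulated in macrophages went from -0.46 to -0.26 and interferon-stimulated in plasma cells from -0.31 to 0.017 under the same setting. With members of at least 100 CPM, Reg in mesothelial cells went from 1.86 to -0.60, STING in fibroblasts from 0.28 to 0.46 and STING in macrophages from -0.19 to -0.42. Complement in fibroblasts went from -0.20 to 0.024, immunoglobulin in fibroblasts from 0.13 to -0.011 and interferon gamma in fibroblasts from 0.98 to 1.45 under the same setting. Interferon gamma in macrophages went from 0.57 to 0.87, oxidative stress in macrophages from -0.16 to 0.0033 and interferon-stimulated in B cells from -1.48 to -1.36 under the same setting. Interferon-stimulated in T cells went from -0.12 to 0.069, interferon-stimulated in fibroblasts from 0.24 to 0.34 and interferon-stimulated in macrophages from -0.46 to -0.57 under the same setting. With members of at least 5 CPM, ductal in macrophages went from -0.40 to 0.29, interferon gamma in macrophages from 0.57 to 0.89 and interferon-stimulated in B cells from -1.48 to -1.36. Interferon-stimulated in fibroblasts went from 0.24 to 0.10 and interferon-stimulated in macrophages from -0.46 to -0.38 under the same setting. As shares of immune cells, the B cell share went from 1.802 to 2.76, the T cell share from 0.22 to 1.18 and the macrophage share from -1.41 to -0.46. The neutrophil share went from -6.22 to -5.27 under the same setting.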

Other observations

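Among the tests in this part, those of acinar free RNA and of neutrophil RNA were chosen only after the result was seen.

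Mesothelial-like cells, the lining cells of the organ surface, made up 4.14% of kept CP cells (95% interval 3.81 to 4.49, 555 cells) and 1.68% of kept CP+EVs cells (1.42 to 1.97, 148 cells). They had the highest medians of the type I and interferon gamma lists among the classes compared, with 20 of 44 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs for the type I list (median log2 ratio 0.37, counting range 0.29 to 0.55, percentile 99.95) and 15 of 22 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower in CP+EVs for the interferon gamma list (median log2 ratio 1.06, counting range 0.90 to 1.15, percentile 100). Ifit3 (2.96-fold, 2.52 to 3.46), Cmpk2 (2.89-fold, 1.98 to 4.20) and Gbp4 (2.91-fold, 2.19 to 3.86) were examples. For both lists the counting range of the median overlapped that of fibroblasts. Saa3 stood at 9150 CPM (9052 to 9249) in CP and 28.9 CPM (19.99 to 40.3) in CP+EVs. The neutrophil attractant Cxcl5 (143-fold, 65.8 to 391), Serpinb2 (81.7-fold, 41.4 to 189) and C5ar1 (129-fold, 23.1 to 5117) were lower, the last at 24.2% of its library level in CP. Plet1 (22.9-fold, 14.5 to 38.1), Spock2 (13.7-fold, 11.6 to 16.3), Gsta3 (10.8-fold, 7.95 to 14.99), Lmo7 (10.003-fold, 7.24 to 14.03) and Igfbp5 (9.61-fold, 9.28 to 9.95) were higher. With means of per-cell values the log2 ratio moved from 4.49 to 5.39 for Plet1, 3.77 to 4.66 for Spock2, 3.43 to 4.62 for Gsta3 and 3.31 to 4.10 for Lmo7, and from -6.26 to -6.94 for Serpinb2. Tff2 was also higher and S100a8 and S100a9 lower, each at between 13.3% and 21.3% of its library level, except S100a8 in CP+EVs at 9.96%. Cluster 10 held most of them in CP and clusters 10 and 31 in CP+EVs. The direction of their share turned with at least 500 genes per cell, to a log2 ratio of 2.08.

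Plasma-like cells made up 1.44% of kept CP cells (95% interval 1.24 to 1.66, 193 cells) and 1.27% of kept CP+EVs cells (1.05 to 1.53, 112 cells). Serpina3f (4.28-fold, 3.56 to 5.18), the prolactin receptor Prlr (3.37-fold, 2.47 to 4.65) and Clu (3.46-fold, 2.48 to 4.90) were higher in CP+EVs, Clu at 24.8% and 24.4% of its library level. Cxcl13 (134-fold, 23.7 to 5313) and Cxcl12 (32.3-fold, 18.7 to 60.97) were lower and stood at 83.6% and 96.9% of their library level in CP. Tff2 (at least 229-fold), Lyz1 and Retnla were also higher, at between 16.8% and 27.2% of their library level in CP+EVs, and Saa3, S100a9, Lcn2 and Ifitm1 lower, at between 19.1% and 35.3% in CP. Their cell cycle list had 0 of 23 measured members at least 1.5-fold higher and 20 at least 1.5-fold lower in CP+EVs (median log2 ratio -1.33, counting range -1.51 to -1.12, percentile 0; -2.35 with means of per-cell values), led by Cenpf (14.1-fold, 5.28 to 53.1) and Cdc20 (8.12-fold, 3.27 to 26.002), while the median over all 5260 genes measured there was -0.42 and median-of-ratios scaling moved it by 0.33. The main plasma cell cluster was 19 in CP and 29 in CP+EVs, and the median depth was 3356 and 12600.5 UMIs per cell. A different mixture of plasma-like cells may therefore give part of the differences in this class, which was not tested. Among other classes, eosinophils were 3.66% of CP and 0.591% of CP+EVs cells, NK cells 0.708% and 1.52%, and endothelial cells 0.0224% and 1.38%.

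Acinar cells were nearly absent from the CP library. Breakage in the loaded suspension is argued against, because free acinar RNA was also low there, at 0.0179% of T cell UMIs against 4.37% in CP+EVs. Acinar cells hidden in other classes are argued against as well, since 0.142% of kept CP barcodes (0.0853 to 0.221) had at least 10% acinar enzyme and Reg UMIs, against 48.0% in CP+EVs. Loss before loading, with broken cells washed away, and a true lack of acinar cells in the CP pancreas both stay open and could each give these values.

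The NF-kB list was lower in CP+EVs T cells, and free RNA of neutrophils in the CP library is a candidate source. Of the 12 members at least 1.5-fold lower, 8 (66.7%) lay within 2 times of the neutrophil markers' level in CP T cells, which was 29.6% of the library level. That is between the 80% that this source would need and the 50% under which it would be excluded, so it stays open. No biological explanation was tested.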
